A study of Homo sapiens with 6 samples.

How the data were processed

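The samples were MCF-7 cells treated with DMSO or TCDD and immunoprecipitated for AHR at 45 min or 24 h, or for AHRR at 24 h, which makes 6 groups of 1 sample. The series description speaks of repeated experiments, but the files carry no value per replicate, so no difference could be set against a spread between replicates. Per the submitters' processing notes, the tools were Bowtie2, SAMtools, MACS2, HOMER and bedtools and the build was hg19; their order, versions and settings are not given in the sources used here.

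The authors deposited 3 annotated peak lists, 1 for each TCDD sample, and 3 class lists. Per the file headers, each peak has a pileup, which is a signal (coverage at the summit), and a fold enrichment, which is a ratio over the caller's background. The file names pair TCDD with DMSO, but whether DMSO libraries were the caller's control is not stated, and whether replicates were pooled is not given either. The authors' peak calling also gave log10 p and log10 q columns, deposited with negative sign and, per the file headers, a factor of 10. A Poisson p computed from pileup and fold matched the p column as plain −log10 within 0.5 for at least 99.995% of peaks in each list, so both columns were read as −log10. The other deposited columns give the position, width, nearest gene, annotation and distance to the TSS. The shortest peak was 126 bp in the 45 min list and 200 bp in both 24 h lists, and why this differs is not stated. The 45 min list also has 62 peaks on sequences outside the chromosomes, and the 24 h lists have 0. Depth per library is not given, and list sizes and scores were not compared as if they were.

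Sequences came from the GRCh37 primary assembly, whose names and lengths fit all peaks on its sequences, with 0 beyond a chromosome end. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and pysam 0.24.0, after indexing with samtools 1.23.1. Peaks overlapped when they shared at least 1 bp. Overlap was compared with 1000 random placements that kept chromosome and width. Shares have exact 95% binomial intervals. Promoter and GCGTG shares were compared with two-sided Fisher's exact tests and Benjamini-Hochberg adjustment over each family, at an adjusted p of 0.05. Median folds within a list were compared with two-sided permutation tests of 100000 permutations. GCGTG was sought on both strands of each peak and of the same width 10 kb to either side. The shuffled background kept each window's dinucleotide counts, and other motifs were sought as fixed words, with bootstrap intervals from 5000 draws for differences between classes. The design foresaw a count test per peak if the files held counts, and they hold none.

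Gene names were matched to a RefSeq gene table of build GRCh38, used for names only, which matched 94.8%, 93.2% and 94.9% of the names in the AHR 45 min, AHR 24 h and AHRR lists. A gene counted as bound when it was the nearest gene of at least 1 peak, and 13 fixed lists were tested against all other protein-coding genes of that table (20056 in all). Named genes followed a rule set before the data were examined. It took every member of the AHR battery with a peak, the nearest genes of the 10 peaks with the highest fold per list and per class, and up to 4 members of each other list with a peak within 10 kb of the TSS, strongest first. Members outside that rule are named only where a count of members is spelled out or as examples of a called list, and were chosen after their values were seen.

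The overlap, permutation test of medians, dinucleotide shuffle, motif search and exact gene list test were tested on simulated data; the thinning, the matched gene lists, the matched promoter windows and the bootstrap differences were not. All 300 overlaps planted in random placements of the AHRR widths on AHR peaks at 24 h were found, all 500 shuffled windows kept their dinucleotide counts, 38 of 1000 random lists of 20 genes passed an unadjusted 0.05, and so did 7 of 100 random splits of the AHRR folds in the permutation test. Alternatives set before the data were examined were other overlap rules (50% of both peaks, summits within 100 bp, extension by 500 bp), the 50% of each list with the highest fold, lists of equal size, leaving out chromosomes 1, 17 and 20, other TSS distances, other strength columns and a longer motif. Peak counts were also taken with peaks within 1 kb merged and on the numbered chromosomes and X alone, and the gene lists with peaks within 10 or 100 kb of a TSS alone. Alternatives added after seeing the data were local shifts of 10 to 50 kb as the random placement, the dinucleotide shuffle, equal-size lists by −log10 q, random gene lists matched on the distance to adjacent start sites, peaks given to the nearest protein-coding TSS of the GRCh37 annotation in place of the authors' nearest gene, and both of these gene choices together.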

Results

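Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map the aryl hydrocarbon receptor (AHR) and its repressor (AHRR) in MCF-7, an oestrogen receptor positive human breast cancer cell line. AHR is a ligand-activated transcription factor of the basic helix-loop-helix PAS family that binds DNA with ARNT. AHRR is a related protein that also pairs with ARNT and is itself the product of an AHR target gene. Cells received the solvent DMSO or TCDD, a dioxin that activates AHR. AHR was mapped at 45 min and at 24 h and AHRR at 24 h, which gave 6 samples in 6 groups of 1 sample each. The files hold 1 peak list for each TCDD sample, and the values have no replicate error. All p-values below compare peaks or genes within these lists, not conditions, and all coordinates are on the human genome build hg19.

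The AHR list at 45 min held 20954 peaks, the AHR list at 24 h 3915 and the AHRR list at 24 h 2811. Median peak widths were 200, 239 and 231 bp, in that order. The pileup, which is the authors' fragment coverage at the summit, had a median of 49, 39 and 40 and a maximum of 411, 405 and 372. The fold enrichment over the caller's background had a median of 4.49, 5.79 and 5.29. Library totals are not given in the sources used here, so the depth behind the lists is unknown and their sizes were compared only as listed.

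The first question was whether the known AHR target genes carried peaks. Of the 20 genes of an AHR battery list fixed before the data were examined, 17 were the nearest gene of at least 1 AHR peak at 45 min, 13 of an AHR peak at 24 h and 11 of an AHRR peak. Among other protein-coding genes the shares were 32.7%, 9.88% and 9.78%. Fisher's exact test gave odds ratios of 11.7, 16.9 and 11.3 with adjusted p = 1.38e-05, 4.55e-08 and 4.54e-06. All 3 lists had peaks nearest to CYP1A1, CYP1A2 and CYP1B1 (xenobiotic-metabolising monooxygenases), NQO1 (a quinone reductase), NFE2L2 (which encodes the oxidative stress regulator NRF2), AHRR, TIPARP (a mono-ADP-ribosyltransferase), UGT1A6, HES1, SOS1 and STC2. ABCG2 and SLC7A5 had AHR peaks at both times and no AHRR peak. ALDH3A1, CYP2S1, EREG and IL1B had AHR peaks at 45 min only, and XDH, SERPINB2 and LRG1 had none.

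Upstream of CYP1A1 on chromosome 15, the AHR list at 24 h held 1 peak from 75018275 to 75019093, with a pileup of 349 and a fold enrichment of 7.41. The AHRR list held 2 peaks that overlapped it, with folds of 5.02 and 5.44. At 45 min the stretch carried peaks with pileups of 398 and 411, the latter the highest of that list, and folds of 2.32 and 1.54. A further peak shared by all 3 lists lay downstream of CYP1A2, where the AHR peak at 24 h ran from 75055722 to 75056319. Its fold was 4.25 for AHR at 45 min, 9.73 for AHR at 24 h and 9.48 for AHRR. The pileups there went another way, with 404, 334 and 199 in that order. The background implied by pileup and fold was 94.3, 33.4 and 20.1. Folds of different lists, here and at the genes below, rest on different backgrounds and do not rank binding between times or factors.

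**Figure D1:**
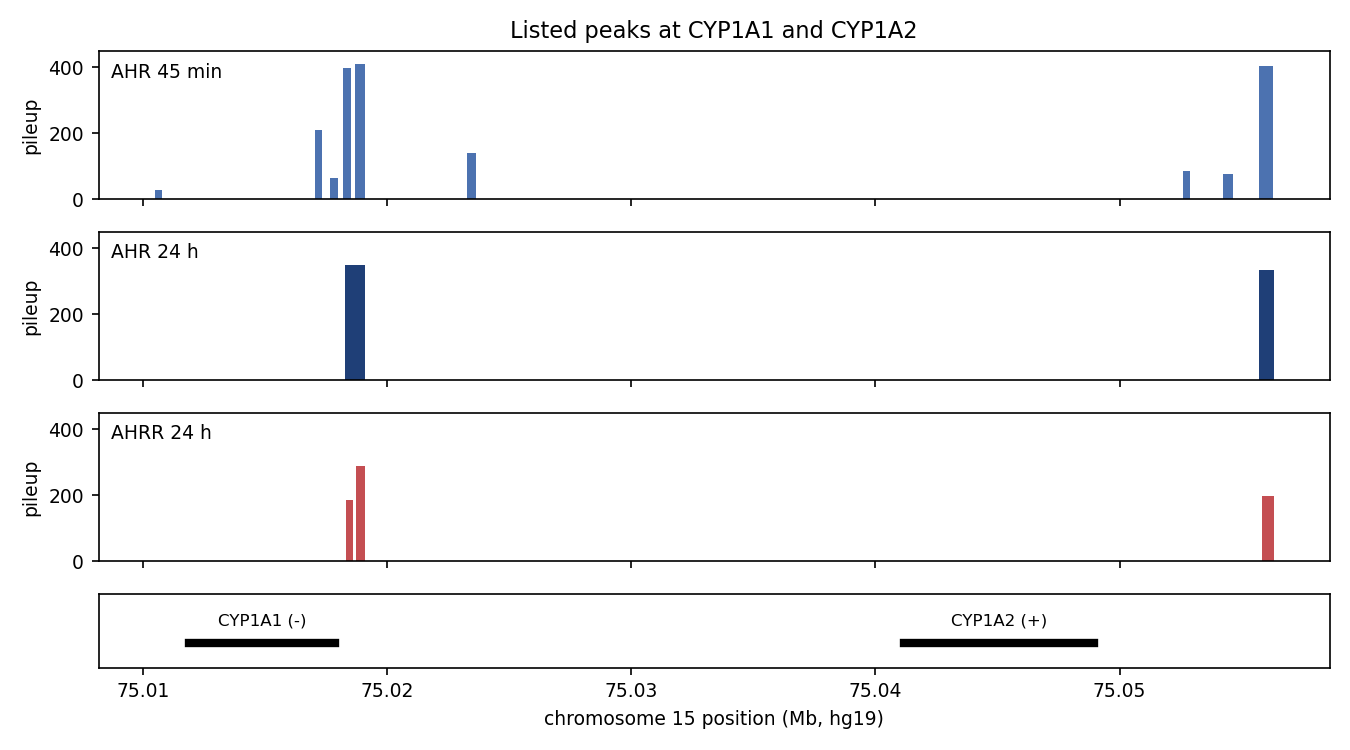
Authors' pileup (vertical axis, fragment coverage at the summit) of every listed peak around CYP1A1 and CYP1A2 on chromosome 15 (horizontal axis, position in Mb), with 1 row per list, bars that span each peak, pileups not scaled between lists and the gene bodies below. The stretch upstream of CYP1A1 and the site downstream of CYP1A2 carry peaks in all 3 lists, while the AHR list at 45 min has 6 peaks nearest to CYP1A1.

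CYP1B1 on chromosome 2 had 12 AHR peaks at 45 min, 4 at 24 h and 3 AHRR peaks. The site from 38323394 to 38323778, at -20263 bp from the TSS by the authors' distance, had a fold of 4.06 for AHR at 24 h and 3.47 for AHRR. The 45 min list placed 2 peaks there, each with a fold of 1.21 and with pileups of 386 and 399. The NQO1 promoter on chromosome 16 carried an AHR peak with a fold of 3.65 at 45 min and 8.1 at 24 h, and an AHRR peak with a fold of 5.53. Near the NFE2L2 start site the folds were 1.35, 5.35 and 2.21. Within the AHRR gene on chromosome 5, the peak from 321758 to 322012 had a fold of 8.01 for AHR at 24 h and 7.69 for AHRR. At TIPARP, the AHR peaks at 24 h (1686 and 28340 bp downstream of the start site) and the AHRR peak (at -33486 bp from it) overlapped no peak of another list. The promoter of UGT1A6, which encodes a glucuronosyltransferase, had an AHR peak at 45 min (fold 7.81) and an AHRR peak (fold 5.65) but no listed AHR peak at 24 h.

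AHR binding at both times was compared next. Of the 3915 AHR peaks at 24 h, 3461 (88.4%, 95% exact Clopper-Pearson interval 87.4 to 89.4%) overlapped an AHR peak at 45 min by at least 1 bp. The median of 1000 random placements was 0.358%, below that exact interval, and no placement reached the observed share (p = 0.001, the smallest that they can give). In the other direction, 3492 of the 20954 early peaks (16.7%) overlapped a peak at 24 h. Intervals cover counting error only. The share fell to 17.6% when the same number of peaks with the highest fold was taken from both lists, and to 53.1% when they were ranked by −log10 q.

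Early peaks that were also listed at 24 h had a median pileup of 142, against 43 for the others. The median fold was 4.49 in both groups (difference 0, two-sided permutation p = 1), so a difference was seen by pileup and not by fold. The core of the AHR response element, GCGTG, was present in 46% of early peaks that were listed again at 24 h and in 31.4% of the others (Fisher's exact test, adjusted p = 4.87e-59). Flanks of the same widths 10 kb away held it in 19.4% and 13.9%. Within 100 bp of the summit, where all windows have 1 width, the shares were 41.4% and 30.7% (exact test, adjusted p = 1.7e-33). The promoter share was 2.89% in peaks listed again and 4.51% in the others (exact test, adjusted p = 7.68e-06), and in the 50% of the list with the highest fold this difference was no longer past the threshold (adjusted p = 0.0933). A total of 448 AHR peaks at 24 h overlapped neither of the other lists. GCGTG was in 12.5% of these, against 9.6% of their flanks (Fisher's exact test, adjusted p = 0.11), and their median pileup was 13.

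AHRR and AHR sites at 24 h overlapped in part. Of 2811 AHRR peaks, 974 (34.6%, exact interval 32.9 to 36.4%) overlapped an AHR peak at 24 h, with a random median of 0.0711% (p = 0.001, the smallest that 1000 placements can give). Local shifts gave a random median of 0.213%, and the limit on open chromatin given above applies here too. From the AHR side, 973 of 3915 peaks (24.9%) overlapped an AHRR peak. A larger share of AHRR peaks, 1801 or 64.1% (interval 62.3 to 65.8%), overlapped an AHR peak at 45 min. AHRR peaks thus divided into 968 with AHR at both times, called co-bound, 833 (29.6%) with AHR at 45 min only, 1004 (35.7%) with AHR at neither time, called AHRR-only, and 6 with AHR at 24 h alone. With the highest-fold peaks in equal numbers, 22.7% of AHRR peaks overlapped AHR at 24 h and 6.47% overlapped AHR at 45 min.

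**Figure D2:**
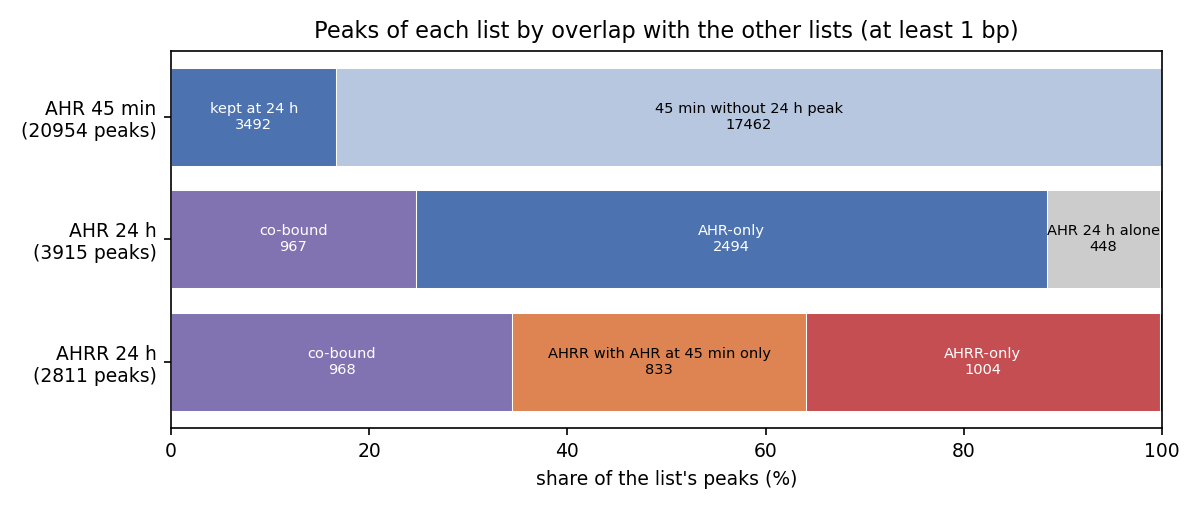
Share of each list's peaks (horizontal axis, %) by overlap of at least 1 bp with the other lists, with the number of peaks in each class. Of the AHRR peaks, 968 were co-bound, 833 had AHR at 45 min only and 1004 had AHR at neither time, and the classes too narrow for a label hold 6 peaks each.

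The authors deposited 3 class lists, with 2525 AHR-only, 969 co-bound and 993 AHRR-only intervals. Parts shared by the AHR peaks of both times gave the same numbers, 2525 without and 969 with AHRR overlap. The 993 deposited AHRR-only intervals were all among the 1004 AHRR peaks found here with AHR at neither time. The deposited classes left out 850 AHRR peaks (30.2%) and 454 AHR peaks at 24 h (11.6%). Most of the former were the AHRR peaks with AHR at 45 min only, which are described as their own class here.

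Peak strength was compared within each list. AHR peaks at 24 h with AHRR had a lower median fold than those without, 5.24 against 6.05, a difference of -0.81 (permutation p = 1e-05, the smallest that 100000 permutations can give, adjusted p = 3e-05). The same peaks had higher pileups, with a median of 80 against 31 and the same smallest p, so the direction turned with the strength column. AHRR peaks with AHR at 24 h had a median fold of 5.58 against 5.19 for the rest (permutation test, adjusted p = 0.00111) and a median pileup of 51 against 35.

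AHRR-only sites lay at promoters far more often than AHR-only sites. The latter are AHR peaks at 24 h that overlapped an AHR peak at 45 min and no AHRR peak. AHRR-only peaks had AHR at neither time. The authors' annotation placed 462 of 1004 AHRR-only peaks (46%, interval 42.9 to 49.2%) in the promoter class, against 61 of 968 co-bound AHRR peaks (6.3%) and 38 of 2494 AHR-only peaks (1.52%). AHRR peaks with AHR at 45 min only were intermediate, with 214 of 833 (25.7%). In the whole AHR lists the promoter class held 889 of 20954 peaks at 45 min (4.24%) and 103 of 3915 at 24 h (2.63%). Fisher's exact test gave an odds ratio of 12.7 for AHRR-only against co-bound (adjusted p = 8.2e-97), 5.14 for AHR at 45 min only against co-bound (adjusted p = 1.32e-30) and 4.28 for co-bound against AHR-only (adjusted p = 4.11e-12). Within 1 kb of a transcription start site (TSS) lay 60.9% of AHRR-only, 38.9% of AHRR peaks with early AHR, 8.57% of co-bound and 2.49% of AHR-only peaks. Introns and intergenic sequence held 42.7% and 53.2% of AHR-only peaks.

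The share of peaks with GCGTG was higher in the AHRR list than in the AHR lists. It was found in 68.6% of AHRR peaks (flanks 10 kb away: 18.6%), in 39.3% of AHR peaks at 24 h (15.5%) and in 33.8% of AHR peaks at 45 min (14.8%). By class the shares were 34.6% in AHR-only, 63.7% in co-bound AHR peaks, 73.7% in AHRR peaks with AHR at 45 min only and 69.4% in AHRR-only peaks. The flanks of the AHRR-only peaks had 18.4% (Fisher's exact test, adjusted p = 4.58e-167). AHR-only peaks had a lower share than co-bound AHR peaks by a difference of -29.1 points (exact test, adjusted p = 9.35e-54). AHRR-only peaks exceeded co-bound AHRR peaks by 5.99 points (exact test, adjusted p = 0.00588), but with the longer motif TNGCGTG the direction turned, with 21.6% of AHRR-only and 28.5% of co-bound peaks, a difference of -6.9 points (exact test, adjusted p = 0.000582). In the 50% of the list with the highest fold the GCGTG difference was 5.46 points (exact test, adjusted p = 0.0864). AHRR-only sites were rich in GC, with a median of 62.7% within 100 bp of the summit against 43.8% for AHR-only sites. Against shuffled sequence with the same dinucleotide counts the AHRR-only share was 66.6% against 37.4%, and the excess was smaller than at co-bound AHRR peaks by 14.9 points (interval 9.96 to 20.2). AHR-only windows had 31.2% against 9.02% in the shuffle, so the excess was lower than that of AHRR-only windows (22.1 against 29.3 points, a difference of -7.15 points, interval -11.4 to -2.96) while the ratio to the shuffle was higher (3.45 against 1.78).

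**Figure D3:**
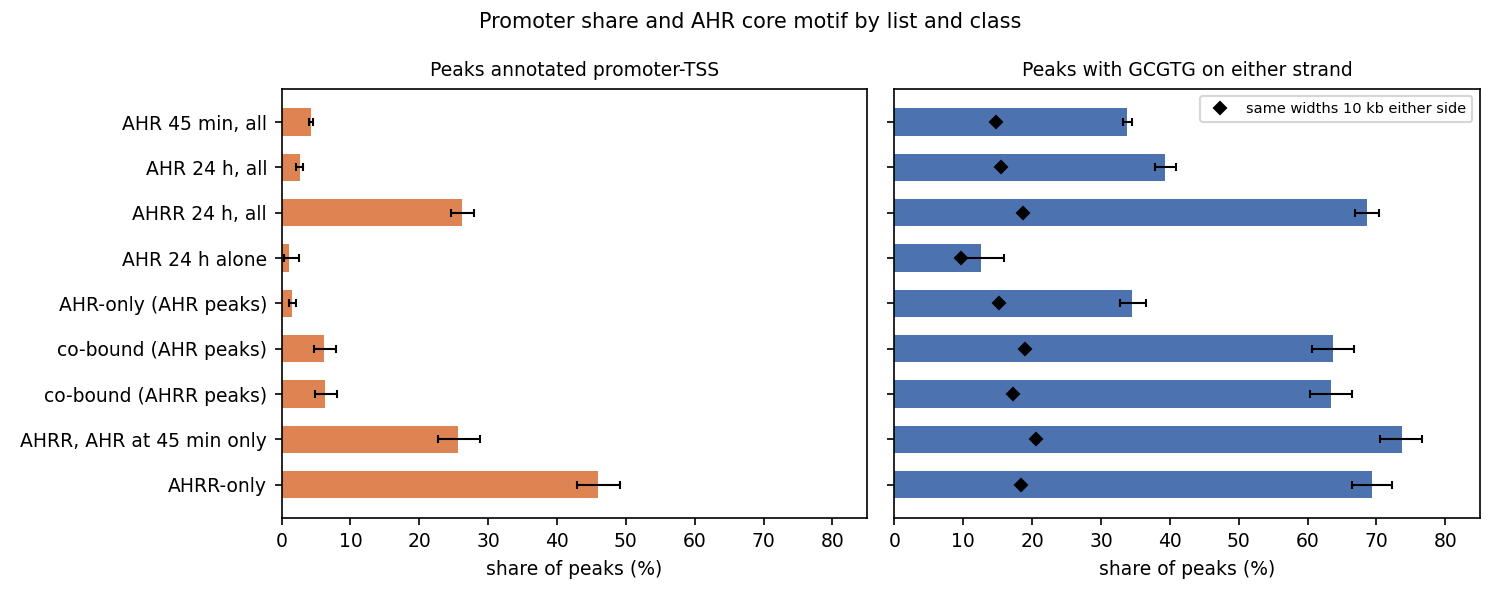
Left, share of peaks annotated as promoter (horizontal axis, %); right, share of peaks with GCGTG on either strand (horizontal axis, %), for each list and class, with exact 95% binomial intervals over peaks as error bars and diamonds for the GCGTG share of the same widths 10 kb either side. The promoter share is 1.12% in AHR peaks at 24 h alone, 1.52% in AHR-only and 46% in AHRR-only peaks, and GCGTG is in 34.6% of AHR-only and 69.4% of AHRR-only peaks.

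Motifs of other transcription factors were counted within 100 bp of the summit, a comparison chosen after the lists were seen. AHR-only windows exceeded their shuffles by 11.5 points for the FOXA motif (FOXA1 is a luminal pioneer factor), 15 points for GATA, 9.38 points for AP-1 and 11.3 points for AGGTCA, the repeated unit of the oestrogen response element. The adjusted p-values of an exact binomial test over discordant windows were 4.09e-55 for FOXA, 1.49e-45 for GATA, 1.46e-29 for AP-1 and 3.08e-24 for AGGTCA. AHR-only windows also exceeded the shuffle for AP-2, TEAD, GRHL, the E-box and the full oestrogen response element, by 0.802 to 5.93 points. The NFY motif CCAAT went the other way, with 23.3% of AHR-only windows against 39.3% of shuffles (-16.1 points, same exact test, adjusted p = 3.06e-34). Large departures from the shuffle thus occurred in both directions, and these motifs were not set against a genomic background. In AHRR-only windows the FOXA and GATA shares differed from the shuffle by 0.398 points each (same exact test, adjusted p = 0.699 and 0.804) and the AGGTCA share by -0.398 points (adjusted p = 0.904), while AP-1 exceeded it by 1.59 points (adjusted p = 0.0188). These windows exceeded the shuffle for SP/KLF by 12.5 points (same exact test, adjusted p = 1.9e-11), ETS by 3.88 (adjusted p = 0.000626), NRF1 by 3.78 (adjusted p = 4.22e-08), CTCF by 3.88 (adjusted p = 9.06e-09), TEAD by 3.88 (adjusted p = 0.00346), the E-box by 2.89 (adjusted p = 0.00317) and CREB by 1.39 (adjusted p = 0.00255). The excess at AHR-only over that at AHRR-only sites was 11.1 points for FOXA (interval 9.29 to 12.9) and 14.6 points for GATA (interval 12.2 to 17).

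**Figure D4:**
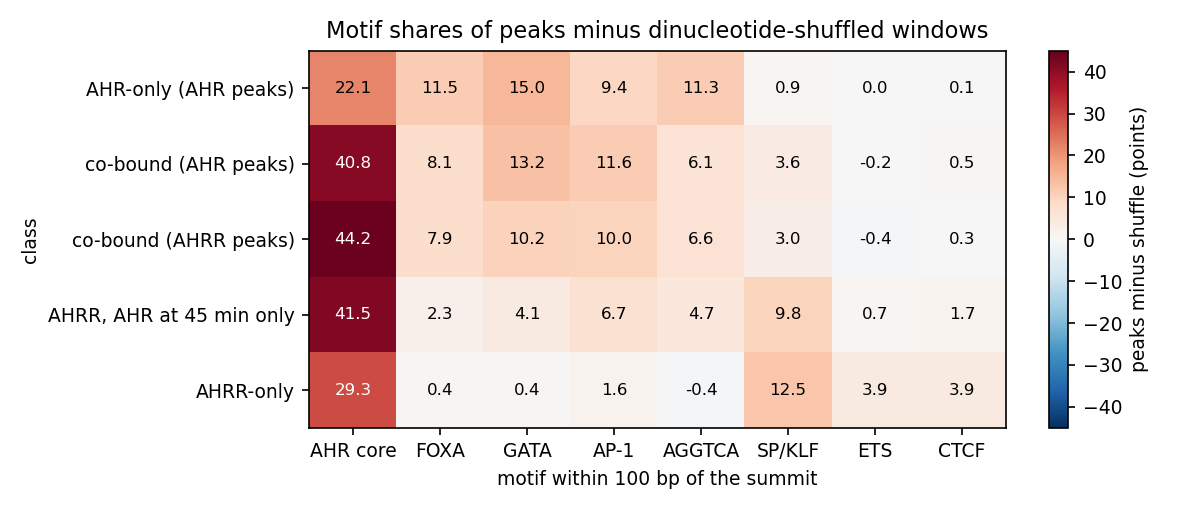
Share of windows with each motif (columns) minus the share in dinucleotide-shuffled windows, in percentage points (colour scale and printed values), for 5 classes of peaks (rows). FOXA is 11.5 points above the shuffle in AHR-only and 0.398 points in AHRR-only peaks, and SP/KLF is 12.5 points above it in AHRR-only peaks.

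Of the 13 gene lists fixed before the data were examined, 9 passed the threshold in the AHR list at 45 min, 5 in the AHR list at 24 h and 4 in the AHRR list (two-sided Fisher's exact test, Benjamini-Hochberg over 39 tests). Luminal transcription factors had the largest share of bound members in each list. All 16 were nearest to an early AHR peak (exact test, adjusted p = 1.67e-07), 13 to an AHR peak at 24 h (adjusted p = 1.45e-09) and 12 to an AHRR peak (adjusted p = 1.91e-08), among them ESR1, which encodes the oestrogen receptor, FOXA1, ELF3, TFAP2C and XBP1. GATA3 had AHR peaks at both times and no AHRR peak. The genes of this list have long neighbourhoods, a median of 420 kb to the midpoints with adjacent start sites against 63.4 kb for all genes. Beside the exact test, the 3 calls held against random lists matched on this length with the same nearest genes (random medians 9, 4 and 2, adjusted p = 0.00156 each, from the smallest p that 10000 random lists can give). Each gene list was tested under 6 alternatives, which were peaks within 10 kb or within 100 kb of a TSS, the 50% of each list with the highest fold, peaks given to the nearest protein-coding TSS, length-matched random lists, and these last 2 changes together. The luminal and AHR battery calls held in 6 of 6 for each list. The luminal share at 24 h rested mostly on distant AHR peaks. Within 10 kb of a TSS it was 3 of 16 (exact test, adjusted p = 0.0265), against 11 of 20 for the AHR battery (adjusted p = 1.63e-11).

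Oestrogen-responsive genes had peaks at 16, 9 and 6 of 20 members in the AHR 45 min, AHR 24 h and AHRR lists (exact test, adjusted p = 0.000107, 0.000273 and 0.0252). Fixed gene lists share members, so their calls are not independent of each other. The 6 members with AHRR peaks (CCND1, MYB, MYC, NRIP1, STC2 and XBP1) all stood in other fixed lists too. Of the 9 with AHR peaks at 24 h, only GREB1, SIAH2 and TFF1 stood in no other list. No test left out the shared members. Both AHR calls held in 5 of 6 alternatives and were lost in the highest 50% by fold (exact test, adjusted p = 0.0723 and 0.391). The AHRR call held in 2 of 6, those with the nearest protein-coding TSS (8 of 20 members, exact test, adjusted p = 0.0048, and 0.037 against matched lists), and was lost in the others (exact test or matched lists, adjusted p = 0.0601 to 1), with 1 of 20 members within 10 kb. Members with peaks included GREB1, with an early AHR peak of fold 9.35 in its first intron, TFF1, with an AHR peak of fold 3.71 at 24 h, and MYB, with an AHRR-only peak of fold 6.73. AP-1 and immediate early genes had AHRR peaks at 7 of 16 members (exact test, adjusted p = 0.00195), a call that held in 6 of 6 alternatives. BHLHE40 and FOSL2 had AHRR peaks in the promoter with folds of 6.06 and 3.7, and ATF3 had one in the 5′ UTR with a fold of 5.26. The early AHR list had peaks at 11 of these 16 (exact test, adjusted p = 0.0168), among them MAFF, a small MAF protein, with a promoter peak of fold 20.3. This early call held in 4 of 6 alternatives (exact test or matched lists, adjusted p = 0.00114 to 0.0319) and was lost in the highest 50% by fold, with 7 of 16 (exact test, adjusted p = 0.144), and against the length-matched lists (adjusted p = 0.051). The AHR list at 24 h had 4 (exact test, adjusted p = 0.0967) and passed in 1 of 6 alternatives, with 6 members by the nearest protein-coding TSS (exact test, adjusted p = 0.0259; 0.0735 to 0.309 in the others, by exact test or matched lists).

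The bHLH-PAS and clock genes passed in the AHR lists, with 12 and 6 of 19 members (exact test, adjusted p = 0.0204 and 0.0231), as did TGF-beta pathway genes, with 12 and 5 of 16 (adjusted p = 0.00255 and 0.0379). Of these exact test calls, each bHLH-PAS call held in 1 of 6 alternatives, within 100 kb at 45 min and with the nearest protein-coding TSS at 24 h, and was lost in the others (adjusted p = 0.0629 to 0.892 at 45 min and 0.121 to 0.284 at 24 h). Each TGF-beta call held in 2 of 6, with the nearest protein-coding TSS and either within 100 kb at 45 min or in the highest 50% by fold at 24 h, and was lost in the others (exact test or matched lists, adjusted p = 0.051 to 0.117 at 45 min and 0.12 to 0.444 at 24 h). NRF2-responsive genes, retinoid pathway genes and phase II enzymes and transporters passed in the early AHR list, with 10 of 15, 10 of 13 and 11 of 18 members (exact test, adjusted p = 0.0252, 0.00497 and 0.0437). Of these exact test calls, the retinoid call held in 4 of 6 alternatives and was lost with the nearest protein-coding TSS (adjusted p = 0.0731, and 0.15 against matched lists). The calls of NRF2-responsive and phase II genes held in 2 of 6 each, with peaks within 10 or 100 kb of a TSS, and were lost in the others (exact test or matched lists, adjusted p = 0.0534 to 0.111). Some lists passed at 24 h under alternatives alone. With the nearest protein-coding TSS these were retinoid genes in the AHR list (5 of 13 members, exact test, adjusted p = 0.0397) and in the AHRR list (6 of 13, adjusted p = 0.00741, and 0.0265 against matched lists), and TGF-beta pathway genes in the AHRR list (6 of 16, adjusted p = 0.0218). NRF2-responsive genes passed in the AHR list with peaks within 10 kb (3 of 15, exact test, adjusted p = 0.0265). In the other alternatives these did not pass (exact test or matched lists, adjusted p = 0.0556 to 0.588). Whether shares differed between the lists was not tested. Retinoid genes with AHRR peaks included STRA6 (fold 9.26), RARG (fold 3.01) and CYP26A1, which encodes a retinoic acid hydroxylase (fold 3.73). Hypoxia-responsive, cell cycle, and inflammation and NF-kB genes passed in no list under the exact test or the 6 alternatives. The promoters of VEGFA (fold 3.98) and KDM3A (fold 4.3) had AHRR peaks, and that of the cell cycle inhibitor CDKN1A had an early AHR peak (fold 5.34) and an AHRR peak (fold 4.42). Genes of other cell types, the negative comparison, had peaks at 8, 5 and 5 of 20 members (exact test, adjusted p = 0.537, 0.078 and 0.078). Their odds ratios at 24 h were 3.03 for AHR and 3.06 for AHRR. The TGF-beta and bHLH-PAS calls in the AHR list at 24 h had odds ratios of 4.13 and 4.19, not far above these. Genes were not matched on expression or open chromatin. With peaks within 100 kb of a TSS, genes of other cell types passed the threshold in the AHR list at 24 h (5 of 20 members against 8.14% of other genes, exact test, adjusted p = 0.0481). In the other alternatives they did not pass there (exact test or matched lists, adjusted p = 0.135 to 1).

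The peaks with the highest fold lay mostly outside these lists. At 45 min they were an intronic peak of PPP2R3B in the pseudoautosomal region, listed on both sex chromosomes with folds of 56.1 and 70.6, then TTC3 (fold 44.8), MIR4671 (41.6), SPATA31A5 (36.1), CHDH (35.9), LINC00906 (34), ZNF726 and HHAT (31.6 each) and LIMK2 (31). Reads from the paired copies of this region cannot be told apart. Only the LINC00906 peak was listed again at 24 h. The AHR list at 24 h was led by PKIA (26.7), LINC00635 (26.6), AC104654.1 (26.4), DISC2 (25.4) and CSNK1G3 (24.8), and further held LINC00708, MIR4328, UBE3D and ATP6V1H with folds down to 22.6. The co-bound peaks were led by DISC2, CSNK1G3, POT1 (19.7), BPIFA4P, KCMF1, MARCKS, CCNI, PRDM1, RP11-165H23.1 and LY86-AS1 (14.2), and LINC00326 and HMGXB4 completed the AHR-only peaks. The AHRR list was led by MRPS33 (26.9), ANXA5 (26.7), STARD13 (25.6) and TTLL12 (25). BRINP3, LSM3, AGPAT9, TNFRSF11B, ITFG2 and FHIT followed with folds of 19.2 to 21.2. Of the 10 highest AHRR-only peaks, those of TTLL12, METAP1 (fold 16.4) and TUBE1 (fold 15.4) lay in promoters. The others were nearest to ANXA5, ITFG2, FHIT, INHBC, C1QTNF7, MIR548AD and CASC3.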

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

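The tests of the shared-peak pileup ratio, of GCGTG against the shuffle, of promoter motifs, of median fold, of copy number, of thinned coverage and of matched promoters were set before their own results were seen; the comparisons of the highest pileups, of promoter shares by strength, of median pileup and of promoter motifs in the promoter class alone were chosen after, as were the motif panel and the low background percentiles behind the coverage ratio.

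The AHR list at 45 min held 62 peaks on haplotype and unplaced sequences of the build, which the placement and motif comparisons do not use. Of these, 45 were on alternate haplotypes and 21 were nearest to IER3. The whole 45 min list had 26 peaks nearest to IER3, so most of that gene's peaks lay outside the chromosomes. Their median fold of 4.59 and median pileup of 48.5 lay near those of the whole list, 4.49 and 49. The lists at 24 h had 0 such peaks, where the same share would give 11.6 for AHR and 8.32 for AHRR. No probability is given for this, because 21 of the 62 peaks share a nearest gene and the peaks are not independent draws. The cause was not tested.

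AHRR-only peaks lay at promoters in 46% of cases. Without chromosomes 1, 17 and 20, left out for copy number gains, the share was 46.1%, so it was not confined to these chromosomes. The outcome set beforehand for copy number, a fall to the AHR-only share, could not occur, because 815 of the 1004 peaks lay elsewhere. This test therefore does not decide on copy number. In the upper 50% of the AHRR list by fold the share was 39.9% against 3.4% of co-bound peaks (Fisher's exact p = 4.72e-52). By pileup it was 52.9% against 8.43% (exact p = 7.55e-53), so weak peaks as the whole source are argued against. A part from weak peaks cannot be told apart, because the strength columns disagree: within the class the promoter share in the upper 50% differed from that in the lower by -12.4 points by fold (39.8% against 52.2%, exact p = 0.00011) and by 13.1 points by pileup (52.6% against 39.4%, exact p = 3.76e-05), and AHRR-only peaks differed from other AHRR peaks by -0.06 in median fold (two-sided permutation p = 0.545) and by -16 in median pileup (permutation p = 1e-05, the smallest that 100000 permutations can give). GCGTG exceeded the shuffle by 29.3 points (interval 25.1 to 33.5), and AHRR-only peaks within 1 kb of a TSS exceeded promoter windows without a peak, matched on GC, CpG count and distance, by 32.5 points (interval 29 to 35.9), so base composition alone is argued against and AHR response elements may contribute. Signal at open promoters cannot be told apart for peaks with or without GCGTG, since 37.4% of shuffles and 41.5% of matched windows without a peak held it. Of 3 promoter motifs, 2 (ETS and NRF1, not NFY) exceeded the shuffle in all AHRR-only peaks. In those of the promoter class 3 of 3 did (NFY in 22.1% against 16%, exact binomial adjusted p = 0.0315). SP/KLF and CTCF, outside this set, exceeded the shuffle by 12.5 and 3.88 points in all AHRR-only peaks. The outcome set beforehand for this explanation also required GCGTG not to exceed the shuffle, and no AHRR-free control was analysed here.

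More AHR peaks were listed at 45 min than at 24 h, and lower coverage at 24 h is a candidate explanation. Thinning the 45 min list by 4.27, the ratio of the low implied backgrounds, left 9310 peaks (9181 to 9412 over draws, 7413 to 9518 over background percentiles) against 3915 listed, and a ratio of 9.07 would be needed to reach that number. This meets the outcome set beforehand against coverage, but it cannot be told apart from a difference in biology, because the ratio is inferred and the thinning simulated with library totals unknown. Of the AHRR sites with AHR at 45 min only, 62.9% kept a passing AHR peak after thinning, against 93.9% of co-bound sites, so some may have been missed at 24 h. A loss of AHR binding between 45 min and 24 h of TCDD stays open, as does a difference in immunoprecipitation efficiency, neither tested.

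AHR peaks at 45 min with the highest pileups, such as those at CYP1A1 and CYP1B1, had low folds, with a median of 1.55 in the 43 peaks over 400. The background implied by pileup and fold had a median of 262.9 in these peaks, against 5.49 at pileups up to 50. Upstream of CYP1A1 it was 266.5 at 45 min (pileup 411) and 46.2 at 24 h. A ceiling alone does not give these folds without a high background, whose cause was not tested. A ceiling on pileups, as removal of duplicate reads gives, is consistent with 2 tests: the highest pileup was 1.01 times that at 24 h despite the inferred coverage ratio of 4.27. The median ratio of 45 min to 24 h pileup in shared peaks was lower in the top 10% by mean log pileup than in the lower 50%, 1.93 against 2.87, a difference of -0.937 (interval -1.05 to -0.822). Whether duplicates were removed is not given in the sources used here, and no biological explanation was tested.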

How the results depend on the processing

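Alternatives set before the data were examined are listed with the processing; random lists matched on gene neighbourhood, peaks given to the nearest protein-coding TSS, local shifts, the dinucleotide shuffle and equal-size lists by −log10 q were chosen after. Of the alternatives for main results, 134 of 154 were the same by 1 of 2 rules. Tests had to keep direction and side of the threshold. Numbers of peaks, of peaks per class and of gene lists past the threshold had to stay within a fixed factor of the main number, and 10 of these moved. Among these were 22 of 22 for overlaps and 28 of 28 for GCGTG against flanks or shuffle. They also included 13 of 18 for GCGTG between classes and 19 of 20 for promoter shares. For overlaps this means only that the share stayed above random placement, not that it kept its size. With equal numbers of the highest-fold peaks, overlap with AHR at 45 min fell from 88.4% to 17.6% of AHR peaks at 24 h. It fell from 64.1% to 6.47% of AHRR peaks, and AHRR overlap with AHR at 24 h fell from 34.6% to 22.7%. AHR peaks at 24 h with AHRR were lower than the rest by fold but higher by 49 in median pileup and by 17.25 in median −log10 q, and early AHR peaks listed again at 24 h, equal by fold, were higher by 99 and 30.2; the cause was not tested. The GCGTG difference between AHRR-only and co-bound AHRR peaks was -6.9 points with TNGCGTG and 5.46 in the highest 50% by fold, that between AHRR peaks with AHR at 45 min only and co-bound ones 3.42 and 6.09, and that between AHRR-only peaks and those with AHR at 45 min only -0.634 in the highest 50%; the cause was not tested. In the 50% of each list with the highest fold the promoter difference between early AHR peaks without and with a 24 h peak was 0.773 points, and the classes held 847 AHR-only peaks, 172 co-bound peaks and 283 AHRR peaks with AHR at 45 min only, as fewer peaks entered. Gene lists past the threshold numbered 9 in the AHR 45 min, 5 in the AHR 24 h and 4 in the AHRR list, against 3, 3 and 3 in the highest 50%, 4, 3 and 3 with matched random lists, 5, 7 and 6 with the nearest protein-coding TSS, and 4, 3 and 5 with both of these changes; the cause was not tested. Of single gene lists, 163 of 216 alternatives were the same, 35 weaker, 7 stronger and 11 reversed. With peaks within 10 kb of a TSS the difference in bound share changed sign for inflammation genes (-8.6 points at 45 min, -2.58 at 24 h), genes of other cell types (-9.85, -2.59 and -5.9 for AHRR), cell cycle regulators (-2.58 at 24 h), and bHLH-PAS and oestrogen-responsive genes with AHRR (-0.636 and -0.899). It also changed for hypoxia-responsive genes within 100 kb (-1.91 at 24 h), inflammation genes with the nearest protein-coding TSS (-0.334 at 24 h) and phase II genes in the highest 50% with AHRR (0.321); the cause was not tested. No paired analysis was possible because each group is 1 sample. Library totals are not given in the sources used here, so how far depth limits the lists is unknown.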

Other observations

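The tests below were chosen after the lists were seen. Of 549 AHR peaks at 24 h with a pileup over 100, 11 overlapped no AHR peak at 45 min (2%, exact 95% interval 1 to 3.56%). The peaks nearest to BMP7 (a TGF-beta family ligand, fold 2.96), C9orf3 (fold 3.57), C5orf55 (fold 4.81) and TNFRSF11B (fold 11.5) also overlapped an AHRR peak. These names are those of the nearest start site and need not be those of the gene that holds the peak. The peak named C5orf55, from 373925 to 374235 on chromosome 5, lay in an annotated intron 69178 bp from that start site. The ANKRD30BL region on chromosome 2 held 5 of the 11, with folds of 1.51 to 1.94. The median implied background was 100.2 at the 11 peaks and 29.3 at the others.

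AHRR-only peaks outside promoters held the CTCF motif (an insulator protein) in 6.83% of windows against 0.369% of shuffled ones (exact binomial test, adjusted p = 9.09e-09), and those in promoters held the NRF1 motif in 7.58% against 0.433% (adjusted p = 6.96e-09). Whether the 2 kinds of peak differ in either motif was not tested.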
